A study of Arabidopsis thaliana with 12 samples.

How the data were processed

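RNA of whole Arabidopsis thaliana seedlings was measured on 12 Affymetrix ATH1 arrays, a 1-colour platform hybridised with biotin-labelled cRNA. Per the labels, the arrays form 4 groups of 3: Col-7 untreated, acn1-2 untreated, Col-7 with sucrose and acn1-2 with sucrose. Groups and replicate numbers were taken from the sample labels. Seedlings grew on agar with MS salts at pH 5.7 and 20 °C under continual light, after 4 days of stratification at 4 °C, and were taken at growth stage 0.70. Sucrose was given at 100 mM. The labels speak of 3 pools of 1000 seedlings, and they do not say whether the replicates of a group were separate cultures.

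The deposited table holds 1 intensity per probe set and array on a linear scale, for 22810 probe sets. The authors had scaled each array so that its 2% trimmed mean was about 100.0; the software that summarised the probes is not given in the sources used here. The table held 233 values of 0, and the smallest positive value was 0.1. No genome build is given in the sources used here, so no coordinates are reported. Probe sets were joined to genes by the platform annotation and to locus names by gene identifier. Of the probe sets, 13513 named 1 gene, 503 named several and 8730 named none in the annotation used here. The gene carrying the insertion, AT3G16910, had 0 probe sets under its name in that annotation, so its own expression was not analysed here.

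The 64 control probe sets were left out, which left 22746. Values under the pooled 25th percentile (14.4) were raised to it as a floor and log2 values were taken. Because the arrays shared a scale, no further normalization was added. Probe sets were tested when their mean over the 12 arrays reached the pooled 40th percentile (29.1), which kept 13764. Of these, 7407 named 1 gene, and 0.359% of the tested values lay at the floor. All 4 groups were fitted in 1 model of group means with limma 3.58.1 in R 4.3.3, with 8 residual degrees of freedom. Moderation by eBayes used no trend and no robust estimate, and the prior had 4.87 degrees of freedom. Tests were two-sided with Benjamini-Hochberg adjustment over the probe sets of a comparison, and an adjusted p under 0.05 was called. The 5 comparisons were acn1-2 against Col-7 in each medium, sucrose against untreated in each line, and the interaction, which is the sucrose effect in acn1-2 minus that in Col-7. The median standard error was 0.13 on the log2 scale, and 0.19 for the interaction. The design, lists, named-gene rule and the alternatives below were chosen before the data were examined, except where stated. Figures were drawn with matplotlib 3.10.9.

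Named genes followed a rule. For each comparison they were the 12 largest rises and 12 largest falls among called probe sets that name exactly 1 gene and whose groups do not overlap; the interaction demanded no such gap. Members of the fixed lists were named in addition. Genes named outside the rule are said to have been chosen after their values were seen.

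The 15 lists, given by locus, were glyoxylate cycle and gluconeogenesis; fatty acid beta-oxidation and oil mobilization; tricarboxylic acid cycle and organic acids; acetate and fermentation; sugar starvation; starch and sucrose metabolism; flavonoid and anthocyanin; photosynthesis; seed storage and late embryogenesis; abscisic acid, cold and drought; heat shock; nitrogen assimilation; cell cycle; root markers; and reference genes. The annotation used here named only part of the listed loci. It named 4 of 29 photosynthesis, 12 of 33 seed, 8 of 26 sugar starvation and 4 of 17 flavonoid loci. A list result therefore covers the measured members only. Each measured locus was represented by its brightest probe set. The 10 lists with at least 3 measured members were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the lists within a comparison. Counts of members are given over all probe sets and adjusted over the list alone. Camera was repeated with an estimated correlation, and fry was run as another set test.

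Replicate numbers were checked for pairing from the correlation of the deviations of same-numbered arrays from their group means. Arrays were described by principal components and by the 3' to 5' ratios of control transcripts, compared with two-sided exact permutation tests. The fit was tested on simulated arrays. Each was the Col-7 untreated mean plus independent normal noise with the residual SD of each probe set. Changes of known size were added to 50 probe sets at each size. At a log2 change of 1 the fit recovered 94% of them, at 0.5 it recovered 24%, and 9 of 13564 unchanged probe sets were called. Arrays that stand apart, correlation between genes and the floor were not simulated, so these figures describe an easier setting than the real arrays.

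The alternatives tried were quantile normalization, no filter, a stricter filter at the pooled 60th percentile (62.3), no floor, a pseudocount in place of the floor, a variance trend with robust estimate, a fit of only the groups compared, the replicate number as a block, the scanner background as a covariate, array weights, a fold of at least 2 beside the adjusted p, and leaving out each array in turn. Leaving out both arrays that stand apart from their groups was added after seeing the data. Not run were the test of AT3G16910 and its repeat without a floor, because no probe set carried that name here.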

Results

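The data were 12 arrays of whole Arabidopsis seedlings in a design of 2 lines and 2 media, with 3 arrays in each of the 4 groups. The lines were Col-7 and acn1-2, a T-DNA insertion line in AT3G16910, which encodes the acetate-activating enzyme ACN1. Each line was grown without sucrose or with 100 mM sucrose. The question was how sugars and organic acids together shape transcript levels. Values are intensities scaled by the authors to a common trimmed mean of about 100.0, and median intensities ran from 41.0 to 47.2 between arrays. The number of arrays limits the precision. The labels do not say that replicates were separate cultures, so each p measures only the spread between these samples, which may be technical. The first principal component held 77.0% of the variance and separated the sucrose arrays from the untreated ones. The acn1-2 untreated replicate 3 and the Col-7 sucrose replicate 3 stood apart from their groups, with an SD of their deviation from the group mean of 0.245 and 0.203.

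The first comparison asked how acn1-2 differed from Col-7 without sucrose, and the named falls included late embryogenesis genes and ICL. AT3G15670, a late embryogenesis abundant (LEA) family gene, had an intensity of 175 ± 34.1 in Col-7 and 7.0 ± 6.42 in acn1-2 (SD, n = 3). All 3 acn1-2 arrays lay at the floor, so this was at least 12.0-fold lower. ICL, the isocitrate lyase of the glyoxylate cycle, fell from 962 ± 190.1 in Col-7 to 184 ± 47.0 in acn1-2 (SD, n = 3), a log2 change of -2.41 (SE 0.18, limma adjusted p 1.6e-05). AT2G47780, of the rubber elongation factor family, changed by -2.83 (SE 0.18, adjusted p 3.53e-06). AT3G02480, another LEA family gene, changed by -3.15 (SE 0.16, adjusted p 4.71e-07). The other named falls were AT5G66780 (-2.32), AT1G04560 (-1.77), the cysteine protease gene AT3G54940 (-1.74), AtLEA4-1 (-1.67), LEA4-5 (-1.45) and LCR67, a plant defensin (-1.44). AT3G17520 and LEA18 had all 3 acn1-2 arrays at the floor and were at least 4.15-fold and at least 3.64-fold lower. AT5G66780 and AT3G54940 had 2 of 3 acn1-2 arrays there, so the size of their falls depends on the floor.

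Of the 13764 probe sets tested, 75 were called without sucrose, 17 higher and 58 lower in acn1-2. At least a 2-fold change was seen in 1 of the higher and 25 of the lower ones. Among the 8 higher ones that name 1 gene, AT1G01500 changed most (0.98, SE 0.16, adjusted p 0.0202). The other 7 changed by 0.52 to 0.75. These rises were fragile: the call of AT1G01500 ended without Col-7 untreated replicate 1 (adjusted p 0.0802) or 3 (0.0951) and without acn1-2 untreated replicate 2 (0.0559), and the other 7 all lost theirs without Col-7 untreated replicate 3 (0.131 to 0.171). Each of these 7 lost its call without 9 to 11 of the 12 arrays, and all 8 did with only the groups compared (0.235 to 0.341) and with no filter (0.0662 to 0.119). The total fell to 29, 46 and 28 without Col-7 untreated replicate 1, 2 or 3, to 46 and 41 without Col-7 sucrose replicate 1 or 2, and to 38, 36 and 37 without acn1-2 sucrose replicate 1, 2 or 3. With both arrays that stand apart left out, a choice made after seeing the data, it was 80.

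The seed storage and late embryogenesis list was lower in acn1-2 as a group without sucrose. Of its 7 measured members, AT3G15670, AT3G17520, LEA18 and LEA4-5 fell (4 called, 6 adjusted over the list alone) and 3 did not pass. These 3 were the oleosin gene AT3G01570 (-1.44, adjusted p 0.0585), the vicilin-like PAP85 (-0.49) and the oleosin OLEO3 (-0.25). The median was -1.45 with floor values as bounds (camera adjusted p 3.94e-15; adjusted p = 0.0343 with an estimated correlation), and -0.55 with no filter, which adds dimmer members. The tricarboxylic acid list had 0 of 17 members called by limma or adjusted over the list alone, with a median of -0.10 (camera adjusted p 0.0247; adjusted p = 0.308 with an estimated correlation). Its call ended without Col-7 untreated replicate 1 (0.089) or acn1-2 untreated replicate 3 (0.158). The call also ended with quantile normalization (0.0866), array weights (0.0511) or both arrays that stand apart left out (0.124). By fry the list was not called (adjusted p 0.108). Its median was -0.06 with array weights, and -0.03 without acn1-2 untreated replicate 3 alone or with the other array that stands apart. The flavonoid list had 0 of 4 called and 2 lower adjusted over the list alone, with a median of -0.21 (camera adjusted p 0.0247; adjusted p = 0.19 with an estimated correlation), and its call ended without Col-7 untreated replicate 3 (0.101) or acn1-2 untreated replicate 1 (0.0751), with array weights (0.0511) and with both arrays that stand apart left out (0.0695). Without a floor its median was -0.47. Of the 8 sugar starvation genes 0 were called by limma or adjusted over the list alone, with a median of -0.14 that ran from -0.24 to -0.01 over the alternatives, and a camera adjusted p of 0.225, which became 0.0356 without Col-7 untreated replicate 3. The 4 photosynthesis genes also had 0 called, at a median of 0.12 that ran from -0.03 to 0.37 over the alternatives (camera adjusted p 0.635, and 0.0296 without acn1-2 untreated replicate 2). In all, 1984 probe sets had an unadjusted p under 0.05, of which 1078 were higher and 906 lower in acn1-2.

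With sucrose, the named LEA genes were again lower in acn1-2, while ICL and AT2G47780 had nearly equal levels in the lines. ICL stood at 2412 ± 194.3 in Col-7 and 2428 ± 102.7 in acn1-2 (SD, n = 3), a log2 difference of 0.01 (SE 0.18). AT2G47780 differed by 0.00 (SE 0.18). AT3G15670 stood at 375 ± 90.6 in Col-7 and 54.5 ± 3.53 in acn1-2, a change of -2.76 (SE 0.17, limma adjusted p 5.51e-06). The other named falls were LEA18 (-2.43), AtLEA4-1 (-2.36), AT3G17520 (-2.30), AT1G04560 (-2.20), AT5G66780 (-2.06), AT3G02480 (-1.99), AT5G07330 (-1.90), AT3G54940 (-1.69), AT4G27450 (-1.59) and LEA4-5 (-1.53). In acn1-2, 2 of 3 arrays of AT5G07330 lay at the floor, so its size depends on it. ATOEP16-2, of the outer plastid envelope, had all 3 acn1-2 arrays at the floor and was at least 4.78-fold lower.

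In all, 29 probe sets were called with sucrose, 0 higher and 29 lower in acn1-2, and 23 of them at least 2-fold. By unadjusted p under 0.05 limma gave 306 higher and 352 lower. With array weights the count was 164, of which 34 were higher, and with both arrays that stand apart left out it was 63. The call of AT3G17520 ended without a floor (adjusted p 0.428), as did those of AT5G66780 (0.517) and AT3G54940 (0.428), and the call of AT3G54940 also ended with no filter (0.0651). The seed list had 4 of 7 members called lower and 6 adjusted over the list alone, with 3 not passing and a median of -1.53 (camera adjusted p 1.96e-27; adjusted p = 0.00524 with an estimated correlation). The 4 flavonoid genes had 0 called by limma, 3 higher adjusted over the list alone, and a median of 0.31 (camera adjusted p 5.75e-06; adjusted p = 0.0116 with an estimated correlation).

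The genes lower in acn1-2 were partly the same in both media, which share no array. Of the probe sets called, 18 were lower in both, against 0.122 for independent lists (Fisher's exact p 3.11e-37 over probe sets, which are not independent). The number lower in both was 8 with the stricter filter, 13 with no filter, 13 with no floor, 27 with array weights and 14 to 19 with 1 array left out. The stricter filter took the dimmer of the 18 out of the test, and the 8 are those that stayed in it. Of the 18, 14 name 1 gene, and they are shown in the plot of genes lower in both media. The median log2 change over the 18 was -1.70 without and -1.94 with sucrose. More of the 18 had acn1-2 arrays at the floor without sucrose than with it. The floor limits the falls more often without sucrose, so these medians do not show a larger fall with sucrose. Across all tested probe sets, which are not independent replicates, the genotype effects of the media correlated at r 0.126. By limma, 0 were called in opposite directions, while 57 passed only without and 11 only with sucrose; a difference between the media was judged by the interaction. Among the genes called only with sucrose and chosen after their values were seen, AT2G25890 (-1.30 with, -1.01 without) had an interaction adjusted p of 0.774.

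**Figure D1:**
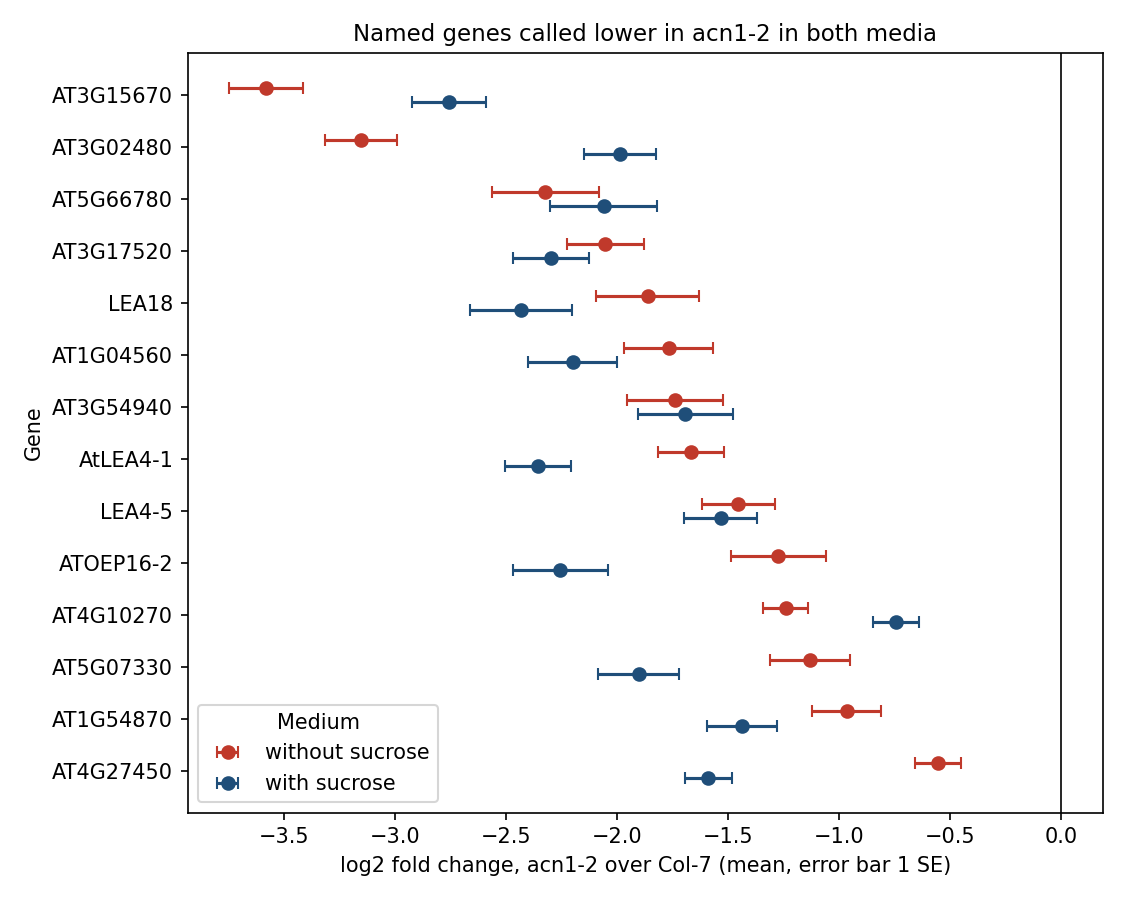
Log2 fold change of acn1-2 over Col-7 (x axis) for the 14 named genes called lower in both media (y axis). Dots are limma estimates from 3 arrays per group and bars are 1 SE, in red without and in blue with sucrose; all lie below 0, from -3.58 for AT3G15670, a bound set by the floor, to -0.56 for AT4G27450.

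The next comparison asked which genes sucrose changed in Col-7, and the named rises included anthocyanin genes. UF3GT, an anthocyanin glycosyltransferase, rose from 40.4 ± 1.46 to 524 ± 22.3 (SD, n = 3), a log2 change of 3.70 (SE 0.10, limma adjusted p 1.01e-10). AT4G14090, an anthocyanin glucosyltransferase, rose to 422 ± 28.8 from a level where 2 of the 3 untreated arrays lay at the floor, so its log2 change of 4.72 depends on the floor. DFR, the dihydroflavonol reductase, rose by 3.39 (SE 0.15, adjusted p 6.34e-09), and the anthocyanin malonyltransferase AT5MAT by 3.16. APL3, a large subunit of ADP-glucose pyrophosphorylase, rose by 3.39 (SE 0.16, adjusted p 9.03e-09). The other named rises were AT1G48660 of the GH3 family (3.12), the serine carboxypeptidase-like scpl35 (2.74), AT3G58060 (2.64, with 2 of 3 untreated arrays at the floor), AT2G47780 (2.63), AT5G62210 (2.55), AT1G53070 (2.54) and AT1G80130 (2.45). The largest falls were AT2G05540 (-5.18, SE 0.29) and the thionin gene AT1G66100 (-4.58, SE 0.19). AT3G15450 fell from 1621 ± 34.9 to 120 ± 10.8 (SD, n = 3). Further falls were AT2G30600 (-3.79), AT2G20670 (-3.57), AT1G23390 (-3.42), AT1G64370 (-3.37), AT1G55960 (-3.28), AT3G22060 (-3.25), the thionin gene THI2.2 (-3.18), AT3G06070 (-3.13) and AT1G52510 (-3.11).

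In Col-7, 6913 probe sets were called for sucrose, 50.2% of those tested, with 3562 higher and 3351 lower. At least a 2-fold change was seen in 562 higher and 870 lower ones. The 3' to 5' ratio of the actin control moved with the medium in both lines. It was 2.90 ± 0.563 untreated and 6.40 ± 0.492 with sucrose in Col-7, and 2.31 ± 0.554 and 6.01 ± 0.605 in acn1-2 (SD, n = 3; exact permutation p 0.1 in each line, the smallest that 3 against 3 arrays can give). The GAPDH ratio moved the other way, from 1.15 ± 0.0698 to 0.851 ± 0.0338 in Col-7 and from 1.24 ± 0.254 to 0.877 ± 0.0486 in acn1-2 (exact p 0.1 in each line). The mean ubiquitin ratio was also lower with sucrose. It went from 2.11 ± 0.195 to 1.96 ± 0.0402 in Col-7 and from 2.33 ± 0.363 to 1.91 ± 0.0440 in acn1-2 (exact p 0.3 and 0.2).

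In acn1-2, the strongest rises with sucrose were AT2G47780, from 27.9 ± 4.08 to 1219.6 ± 29.7 (SD, n = 3), a log2 change of 5.46 (SE 0.18, limma adjusted p 4.03e-10), and AT4G14090 (5.17, with 2 of 3 untreated arrays at the floor). UF3GT rose by 4.25 and DFR by 4.22. ICL rose by 3.76 (SE 0.18, adjusted p 6.8e-09). Others that rose were APL3 (3.43), AT2G23910 (3.22) and scpl35 (3.09). AT1G48660, AT5G62210, AT5MAT and AT4G17470 had all 3 untreated acn1-2 arrays at the floor and were at least 15.5-fold, at least 15.0-fold, at least 12.4-fold and at least 8.53-fold higher with sucrose. The falls were AT1G66100 (-5.36), AT2G05540 (-5.32), AT2G30600 (-3.89), AT1G55960 (-3.72), AT1G62510 (-3.71), AT2G20670 (-3.60), AT1G23130 (-3.54), AT3G15450 (-3.44), AT3G22060 (-3.39), AT1G23390 (-3.37) and AT4G17245 (-3.33). AT1G66100 and AT3G22060 had 2 of 3 sucrose arrays at the floor, so the size of their falls depends on it. AT1G64370 had all 3 sucrose arrays at the floor and was at least 12.2-fold lower. In all, 7837 probe sets (56.9%) were called, 3766 higher and 4071 lower, of which 785 and 993 changed at least 2-fold. The balance of directions turned under quantile normalization, to 4112 higher and 3727 lower, and with the stricter filter, to 3140 higher and 2953 lower.

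Of the flavonoid and anthocyanin list, all 4 measured members rose with sucrose in each line (4 adjusted over the list alone), with medians of 3.55 in Col-7 and 4.24 in acn1-2, to which AT4G14090 and AT5MAT contribute untreated values at the floor. The camera adjusted p was 2.35e-06 and 3.33e-06, and both calls held with an estimated correlation (adjusted p = 0.0161 and 0.0174). In the tricarboxylic acid list, 12 of 17 members rose, 1 fell and 4 did not pass in each line (12 higher and 1 lower adjusted over the list alone). AT5G08300, a succinyl-CoA ligase gene, rose by 0.79 in Col-7 and 0.85 in acn1-2, AT5G55070 of the oxoglutarate dehydrogenase complex by 0.94 and 1.23, and SDH2-1 of succinate dehydrogenase by 0.51 and 0.68. The cytosolic isocitrate dehydrogenase cICDH fell by 0.30 and fell by 0.27. The list medians were 0.53 and 0.68 (camera adjusted p 0.00154 and 2e-04; adjusted p = 0.164 and 0.0945 with an estimated correlation). In the seed list, 6 of 7 members rose in Col-7 and 5 of 7 in acn1-2 (6 and 5 adjusted over the list alone), among them LEA4-5 (1.31 and 1.23) and OLEO3 (1.43 and 1.26), with medians of 1.09 and 1.11. Its camera adjusted p was 0.0053 and 0.0142, and adjusted p = 0.398 and 0.401 with an estimated correlation; with the stricter filter it was 0.0814 and 0.0596. With no filter the acn1-2 median was 0.23. AT3G15670, AT3G17520 and LEA18 had all 3 untreated acn1-2 arrays at the floor, so the acn1-2 count and median of this list depend on it.

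Of the sugar starvation list, 7 of 8 members fell and 1 did not pass in Col-7 (7 adjusted over the list alone). MCCA, a subunit of methylcrotonyl-CoA carboxylase in leucine breakdown, changed by -2.20, AKINBETA1, a subunit of the SnRK1 kinase, by -1.97, and IVD, the isovaleryl-CoA dehydrogenase, by -1.10. The median was -0.77 (camera adjusted p 0.0029; adjusted p = 0.246 with an estimated correlation). In acn1-2, 5 fell, ETFBETA, an electron transfer flavoprotein subunit, rose by 0.73, and 2 did not pass (6 lower and 1 higher adjusted over the list alone). That median was -0.74 (camera adjusted p 0.0482; adjusted p = 0.401 with an estimated correlation). The acn1-2 call ended without Col-7 untreated replicate 2 (0.0535), acn1-2 untreated replicate 1 (0.0847) or 2 (0.0865), Col-7 sucrose replicate 2 (0.0549) or 3 (0.05) and acn1-2 sucrose replicate 3 (0.0638), and also with the stricter filter (0.251), quantile normalization (0.0522) and the scanner background as a covariate (0.0553). All 4 measured photosynthesis genes, of 29 loci listed, fell in each line (4 adjusted over the list alone). PRK, the phosphoribulokinase, changed by -1.26 in Col-7 and -1.49 in acn1-2, and RCA, the Rubisco activase, by -0.74 and -0.84. The list medians were -0.87 and -0.96 (camera adjusted p 0.0282 and 0.0417; adjusted p = 0.398 and 0.401 with an estimated correlation). Its call ended with the stricter filter in Col-7 (0.0502) and acn1-2 (0.0596), and in acn1-2 without untreated replicate 1 (0.0795) or 3 (0.0542).

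**Figure D2:**
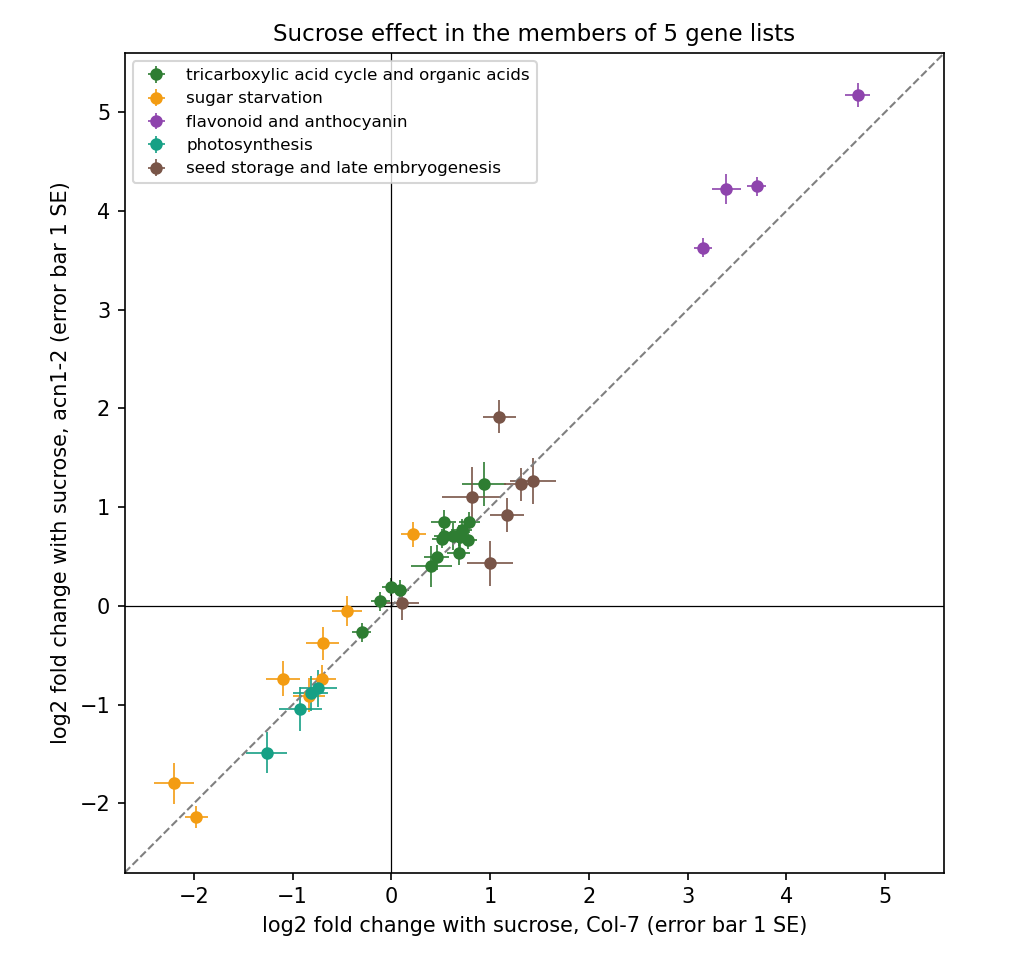
Log2 fold change with sucrose in Col-7 (x axis) and in acn1-2 (y axis) for each measured member of 5 gene lists, coloured by list. Dots are limma estimates from 3 arrays per group, bars are 1 SE and the dashed line marks equal effects; the 4 flavonoid and anthocyanin genes lie above it, at 3.16 to 4.72 in Col-7 and 3.63 to 5.17 in acn1-2, with untreated arrays of AT4G14090 and AT5MAT at the floor in both lines.

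The remaining lists were not called by camera in either line. By fry, starch and sucrose metabolism (adjusted p 1.67e-07 and 2.44e-07) and acetate and fermentation (0.00408 and 0.000554) were called. So were root markers (0.0306 and 0.0428) and reference genes (0.0201 and 0.0428). Fry asks whether a list changes at all, not whether it changes more than other genes. With 50.2% and 56.9% of all tested probe sets called, its calls do not set these lists apart. For starch and sucrose metabolism, APL3 and the branching enzyme SBE2.2 (0.43) rose and the invertase gene AT1G62660 fell by 0.32 in Col-7, while in acn1-2 APL3 rose, AT1G62660 fell by 0.31 and SBE2.2 did not pass (3 and 2 adjusted over the list alone; camera adjusted p 0.293 and 0.339). The Col-7 list was called with no filter (0.0417). For acetate and fermentation, the acetyl-CoA synthetase ACS (0.52 and 0.47) and the lactate dehydrogenase AT4G17260 (0.60 and 0.72) rose in both lines, and ALDH2C4 fell by 0.34 in Col-7 with a change of -0.10 in acn1-2 that did not pass (3 and 2 adjusted over the list alone; camera adjusted p 0.396 and 0.308). Of 3 beta-oxidation genes 0 were called by limma in Col-7 and 1, SDRB (0.36), in acn1-2 (0 and 0 adjusted over the list alone; camera adjusted p 0.699 and 0.585). The root hair expansins EXPA18 (0.87 and 0.93) and EXPA7 (0.45 and 0.35) rose in both lines and PYK10 did not pass (2 and 2 adjusted over the list alone; camera adjusted p 0.396 and 0.339). Of 3 reference genes AT4G34270 rose (0.28 and 0.29) and 2 did not pass (0 and 0 adjusted over the list alone; camera adjusted p 0.396 and 0.461). Lists with fewer than 3 measured members were not tested as groups. The glyoxylate list held ICL and PPDK, which rose by 0.77 in Col-7 and 1.09 in acn1-2. The abscisic acid list held COR47 (-0.03 and 0.18, not passing) and LTI30 (0.24, not passing, and 0.49, adjusted p 0.00116). The heat shock gene ATHSP22.0 (-0.12 and 0.03) did not pass. The cell cycle gene PRL rose in Col-7 (0.35, limma adjusted p 0.0285) with 0.18 in acn1-2 (adjusted p 0.213). The annotation used here named 0 of the 12 nitrogen assimilation loci, so that list was not analysed.

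The sucrose effects of the lines, which share no array, went largely the same way. Of the called probe sets, 2935 were higher and 2857 lower in both, against 974.6 and 991.1 for independent lists, and the effects correlated at r 0.925 across probe sets, which are not independent replicates. Called in opposite directions were 4, chosen after their values were seen: ATG8D (-0.28 in Col-7, 0.34 in acn1-2) and 3 that do not name 1 gene (0.38 and -0.48, -0.61 and 0.33, 0.38 and -0.39). Their interaction adjusted p was 0.213, 0.184, 0.14 and 0.267 in that order.

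The interaction asked whether the sucrose effect differed between the lines, and the named genes with a positive difference were those lower in acn1-2 without sucrose. AT2G47780 rose by 2.83 more in acn1-2 than in Col-7 (SE 0.25, limma adjusted p 0.000686). ICL rose by 3.76 in acn1-2 and 1.34 in Col-7, a difference of 2.42 (SE 0.25, adjusted p 0.00222). AT1G73120 rose by 2.16 and 0.66, a difference of 1.498 (SE 0.21, adjusted p 0.0189). AT1G06000, a flavonol rhamnosyltransferase, rose by 2.73 and 1.75, a difference of 0.99 (SE 0.15, adjusted p 0.0422). AT4G27450 went the other way: it fell by 1.04 in acn1-2 and changed by -0.01 in Col-7 without passing, a difference of -1.03 (SE 0.15, adjusted p 0.0189). The plot of these genes by array shows the values.

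Of the probe sets tested, 8 had a called interaction, 6 positive and 2 negative, and 1380 had an unadjusted p under 0.05, 641 positive and 739 negative. Of the 3 that name no gene, chosen after their values were seen, the positive ones had differences of 2.203 and 1.24. No difference is given for the negative one, since all untreated arrays of both lines lay at the floor and its test only repeats the genotype effect with sucrose. The total was 5 without acn1-2 untreated replicate 1 or 2 or acn1-2 sucrose replicate 1, 4 without Col-7 sucrose replicate 1 or 2 or acn1-2 sucrose replicate 3, and 19 without Col-7 sucrose replicate 3, 9 positive and 10 negative. It was 13 with the stricter filter, 18 with a variance trend and robust estimate, 22 with array weights, and 13 with both arrays that stand apart left out, 7 positive and 6 negative. ICL and AT2G47780 were called under every alternative tried. With the replicate number as a block, AT1G73120, AT1G06000 and AT4G27450 were not called. AT1G73120 lost its call without acn1-2 untreated replicate 1 (adjusted p 0.0582) or 3 (0.0534), Col-7 sucrose replicate 1 (0.0549) or 2 (0.0788) and acn1-2 sucrose replicate 1 (0.0882) or 3 (0.0832), with no filter (0.0933) and with both arrays that stand apart left out (0.0595). AT1G06000 lost its call without Col-7 untreated replicate 1 (0.0748), acn1-2 untreated replicate 1 (0.1), 2 (0.0653) or 3 (0.102), Col-7 sucrose replicate 1 (0.118) or 2 (0.191) and acn1-2 sucrose replicate 1 (0.183), 2 (0.197) or 3 (0.0955). It also lost its call with no filter (0.0634), the scanner background as a covariate (0.0855) and both arrays that stand apart left out (0.0595). AT4G27450 lost its call without Col-7 untreated replicate 1 (0.0729) or 2 (0.0692), acn1-2 untreated replicate 1 (0.0582) or 2 (0.0653), Col-7 sucrose replicate 1 (0.079) or 2 (0.0971) and acn1-2 sucrose replicate 1 (0.0882) or 3 (0.0832).

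The flavonoid and anthocyanin list rose more with sucrose in acn1-2 than in Col-7. Its 4 members had 0 called by limma and 4 adjusted over the list alone, with DFR at 0.83 and UF3GT at 0.55. No value is given for AT4G14090 and AT5MAT, which had untreated arrays at the floor in both lines. The median, which includes them, was 0.51 (camera adjusted p 1.3e-05; adjusted p = 0.0239 with an estimated correlation), and 0.82 without a floor. The seed list had 0 called by limma and 1 adjusted over the list alone, at a median of -0.08 (camera adjusted p 0.893). Without a floor that median was 0.29 (0.0203). AT3G15670, AT3G17520 and LEA18 had all 3 untreated acn1-2 arrays at the floor, so their differences and the list median depend on it. The values with the floor therefore do not show that the lines responded alike. Of the 8 sugar starvation genes 0 were called by limma or adjusted over the list alone, at a median of 0.34 (camera adjusted p 0.195). The adjusted p was 0.0291 without Col-7 untreated replicate 3 and 0.0333 without Col-7 sucrose replicate 1. With both arrays that stand apart left out the median was 0.05 (adjusted p 0.872).

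**Figure D3:**
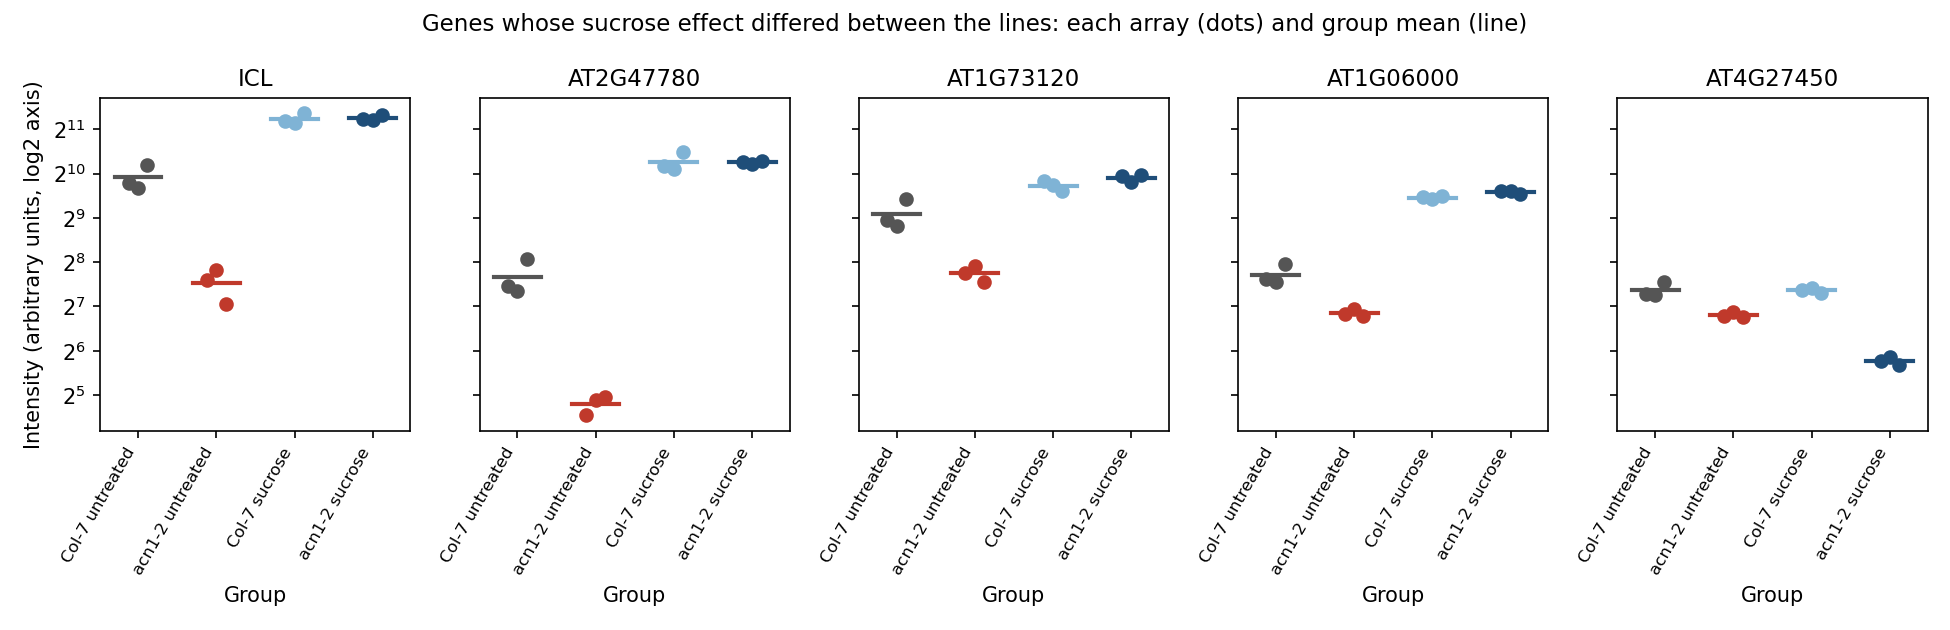
Intensity in arbitrary units on a log2 axis (y axis) of the 5 named genes with a called interaction, by line and medium (x axis). Dots are single arrays, 3 per group, and lines are group means; ICL averages 962, 184, 2412 and 2428 in Col-7 untreated, acn1-2 untreated, Col-7 sucrose and acn1-2 sucrose.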

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

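All tests of explanations in this part were chosen after the results were seen; the counts over other splits of the arrays were planned.

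The results below stand out because the interaction test called them. The difference was 2.83 for AT2G47780, 2.42 for ICL, 2.203 and 1.24 for a pair of probe sets that name no gene, 1.498 for AT1G73120 and 0.99 for AT1G06000 on the log2 scale. It was -1.03 for AT4G27450. The fit gave -1.92 for another probe set that names no gene, but all its untreated arrays lay at the floor in both lines, so this repeats the genotype effect with sucrose and a difference in the effect of sucrose was not measured. The flavonoid and anthocyanin list differed by a median of 0.51, to which AT4G14090 and AT5MAT contribute untreated values at the floor.

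Of the 200 reassignments of the lines within each medium, 100 were drawn. Of these, 2 called at least as many probe sets for the interaction as the real 8, the real one included. The other one called 54, and the next highest was 4. Reassigning the lines also mixes the genotype effects into the groups, so these counts cannot exclude chance for the interaction itself. The 54 came from exchanging the lines in the sucrose medium alone, which turns the contrast into the sum of both genotype effects with its sign turned and so reflects a structure of the samples, the difference between the lines. For the comparisons of 3 against 3 arrays, the 10 splits cannot give a share under 0.05; in each, 1 split, the real one, reached the count. The real and the highest other count were 75 and 3 for the lines without sucrose, 29 and 1 with sucrose, 6913 and 0 for sucrose in Col-7 and 7837 and 0 in acn1-2.

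The 6 probe sets with a positive interaction were called lower in untreated acn1-2 and were not called between the lines with sucrose, where 1 that names no gene stood at 1242 ± 23.8 in Col-7 and 1511 ± 57.5 in acn1-2 (SD, n = 3). The arrays that stand apart are not the whole source, since 4 of the 6 were still called without them, and the others, AT1G73120 and AT1G06000, kept differences of 1.34 and 0.97. A ceiling of the arrays was argued against for AT1G06000, AT1G73120 and AT2G47780, which reached at most 1426.6 on any sucrose array, under 1574.65, which is 50% of the lowest maximum among the sucrose arrays; the unnamed probe set above reached at most 1577.6, and its Col-7 mean lay below that of acn1-2, which a ceiling shared by the lines would not produce. For ICL and the other unnamed probe set, whose means lie above that level, a ceiling could have hidden a difference between the lines with sucrose: this stays open, since 0 of 329 probe sets as bright were called between the lines there by limma, which excludes nothing where only 0.211% of all tested probe sets were called. A response to the insertion that sucrose removes may account for the low untreated values, as a hypothesis.

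Of the 18 probe sets lower in acn1-2 in both media, AT3G15670, AT3G17520, LEA18 and LEA4-5 belong to the seed storage and late embryogenesis list. The arrays that stand apart are not their source, since 17 of the 18 were still called lower in both media without them. With no floor 13 were. With the stricter filter 8 were still called, and the others had means under its threshold of 62.3 and were not tested. Of the 14 named genes, 12 lie more than 500 protein-coding loci from AT3G16910 (85.7%, exact 95% interval 57.2% to 98.2%). Variants on a linked chromosome segment of that size cannot lie in these 12 genes themselves. A linked variant that acts on genes elsewhere stays open, since the positions of the genes cannot test it. For the 2 within, AT3G15670 and AT3G17520, a variant in the gene itself also stays open. In that segment lie 3.88% of the tested loci (Fisher's exact p 0.1 for the share of the named genes against it). Seed RNA, from seed coats or from seedlings less advanced in germination, may have made up a larger share in Col-7 than in acn1-2. This may account for part of the lower levels in acn1-2 and stays open. The members fell unevenly, by as little as -0.247 for OLEO3 (heterogeneity p 3.53e-46). That p treats members on the same arrays as independent and bounds at the floor as measured values, so its size should not be relied on. A source outside the seed for such members was not measured. The line itself, or another variant it carries, remains an untested biological explanation.

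More than 50% of the probe sets were called for sucrose in each line. After quantile normalization 7010 were called in Col-7, so the count there did not hang on the choice between this and the deposited scaling. Both set the arrays to a common level, so a shift that such scaling creates could remain in both. Such a shift would move all log2 changes of a comparison by the same amount. Yet 562 probe sets were higher and 870 lower by at least 2-fold in Col-7, and 785 and 993 in acn1-2. The log2 changes had an SD of 0.66 and 0.73 over all tested probe sets, at a median SE of 0.13. These values argue against a common shift as the whole source of the calls. The division into higher and lower could still depend on it. More degraded RNA with sucrose stays open, since the 3' to 5' ratios of the controls went different ways. The mean ratios of GAPDH and ubiquitin were lower with sucrose, and that of actin was higher. The GAPDH ratio changed by -0.302 in Col-7. It was at most 0.920 on any sucrose array and at least 0.958 on any untreated one. The mean ubiquitin ratio changed by -0.150 in Col-7 and -0.425 in acn1-2 (exact permutation p 0.3 and 0.2). The actin ratio rose with sucrose, by 3.50 in Col-7 and 3.70 in acn1-2, which was not explained. The response to sucrose itself also remains, as a hypothesis.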

How the results depend on the processing

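Leaving out both arrays that stand apart was chosen after seeing the data; all other alternatives were planned. Of the called values among 85 named gene values and 50 list medians, 0 changed direction; other probe sets were not followed. Quantile normalization turned the balance of the sucrose calls in acn1-2 to 4112 higher and 3727 lower, and the stricter filter to 3140 higher and 2953 lower. The number lower in acn1-2 in both media (18) was 8 with the stricter filter, 13 with no filter or no floor, 27 with array weights, and 14 to 19 with 1 array left out. The count for the lines without sucrose (75) was 42 with no filter, 25 with only the groups compared, 46 with the scanner background as a covariate, 26 at a fold of at least 2, and 28 to 92 with 1 array left out. The count for the lines with sucrose (29) was 10 with the stricter filter, 17 with no floor, 164 with array weights, 63 with both arrays left out, and 21 to 43 with 1 array left out. The counts for sucrose were 1432 in Col-7 and 1778 in acn1-2 at a fold of at least 2, and 5832 to 7580 and 6758 to 7965 with 1 array left out. The interaction count (8) was 13 with the stricter filter, 18 with a variance trend and robust estimate, 22 with array weights, 13 with both arrays left out, and 4 to 19 with 1 array left out. The fold threshold, the filters and the smaller fits change how many probe sets or arrays are tested or admitted by construction; for the other settings the cause was not tested. For the 85 named gene values, 1778 repeats kept their call and 157 lost it, and for the 50 list results 1191 kept their side of the threshold, 35 lost and 14 gained a call. Quantile normalization gave 86, 26, 7010, 7839 and 8 for the 5 comparisons in the same order. The test of AT3G16910 and its repeat without a floor were not run. Low signal limits the folds of genes near the floor of 14.4.

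Replicate numbers did not pair the samples: the correlations of same-numbered arrays ran from -0.0953 to 0.139, and 3 of 18 exceeded 0.1. With the replicate block the counts were 41 and 34 for the lines without and with sucrose, 6772 and 7749 for sucrose in Col-7 and acn1-2, and 6 for the interaction.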

Other observations

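Both tests of hypotheses in this part were chosen after the result was seen.

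The acn1-2 seedlings without sucrose also had lower levels of a few further genes, chosen after their values were seen: AT2G38905 (-1.07, limma adjusted p 0.0137), AT3G48460 (-1.01, adjusted p 0.0235), BETA-VPE, a vacuolar processing enzyme (-0.57, adjusted p 0.0393), and STOMAGEN, a secreted regulator of stomatal density (-0.62, adjusted p 0.0393). With sucrose, BGLU19, a beta-glucosidase (-0.70, adjusted p 0.038), AT3G11930 (-0.79, adjusted p 0.0164) and AT1G62510 (-0.85, adjusted p 0.0493) were lower in acn1-2; their interaction adjusted p was 0.349, 0.279 and 0.121, so a difference between the media was not shown.

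The first hypothesis was that untreated acn1-2 lies further from the sucrose state than untreated Col-7. On an axis from the mean untreated to the mean sucrose profile, the score was -0.555 in acn1-2 and -0.445 in Col-7, a difference of -0.110 that ran from -0.132 to -0.0855 with 1 array left out. The axis was built from all 12 arrays, the scored ones included, and was kept fixed when an array was left out. That range therefore does not show how far the axis itself depends on single arrays. The difference has the sign that the hypothesis predicts, but the exact permutation p of 0.1 is the smallest that 3 against 3 arrays can give. The hypothesis stays open.

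A further hypothesis was that acn1-2 without sucrose is more sugar-starved than Col-7, so that starvation genes are raised. The mean log2 difference of the 8 starvation genes was -0.128 (95% interval -0.370 to 0.115, exact permutation p 0.3). A rise of these 8 measured genes, of 26 loci listed, by 0.5 or more lies outside that interval. That size was set after the median was seen, so this is not an independent test. A smaller rise, or a rise of the loci not measured, may remain.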
